A study of Mus musculus with 4 samples.

How the data were processed

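Gene expression was measured on 1-colour Agilent mouse arrays in 4 samples of islets, the hormone-secreting cell clusters of the pancreas, isolated from C57BL/6 mice. The labels put 2 samples in the vehicle group and 2 in the group treated with GKA, a glucokinase activator, and number the samples of each group 1 and 2. They do not say whether the samples of a group came from separate mice or separate cultures, so the p-values measure only the spread between these samples, which may be technical.

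The intensity of each spot, a background-subtracted and detrended fluorescence value on a linear scale, was made with Agilent Feature Extraction per the file headers, which give version 10.7.3.1, while the submitters' processing notes name version 9.1. These intensities were not scaled between arrays. The authors also deposited a table for the whole series that holds 1 intensity per group and probe and 1 ratio of GKA over control. All of its group intensities for probes with a single spot equalled the plain mean of the 2 arrays within 0.1%, and its ratio equalled the quotient of the group values. The median ratio over all probes in the authors' deposited table was 0.841, and 78.9% of its ratios were below 1. The ratios therefore carry the unscaled difference in probe signal between the groups, and the array files were used here instead. Control spots did not share this difference, being brighter on the GKA arrays (E1A spike-ins by 0.22, bright corner by 0.76 on the log2 scale). Whether it came from the samples or from the arrays was not tested.

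The main values were log2 of the processed intensity minus the 75th percentile of each array. Control spots and spots marked as non-uniform or population outliers were left out, and spots of a probe were averaged on the log2 scale. No spot was marked as saturated on any array, a count of 0 in each. Of 39429 non-control probes, 33697 carried a gene name in the authors' deposited table and 5732 carried none, and the latter stayed out of the gene tests. Probes were kept when well above background on both arrays of at least 1 group, which left 24481 probes. Each gene was represented by its probe with the highest mean signal, and 17173 of 26265 genes on the array were tested. Probes of 2 genes were left out because no unmarked spot was left on at least 1 array. Among the 637 changed genes with several kept probes, 55 had probes that pointed in opposite directions. Gene names are those of the array's design. Entrez identifiers matched 15848 of the tested genes to a current mouse symbol in a RefSeq gene table of assembly GRCm38.p6, used only for names, and the symbol differed for 2108. Coordinates are probe positions on build mm9, as in the authors' deposited table.

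GKA and vehicle were compared with limma version 3.58.1 (lmFit and eBayes) in R version 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom and 3.33 from the prior. An exact permutation of these 4 arrays cannot give a two-sided p below 0.333, so no permutation test is reported. Where a gene was not well above background on any array of a group, only a bound is given: the mean log2 value of the brighter group was set against the mean, over the dimmer group's arrays, of the higher of the gene's own value and the lowest value among probes well above background on that array. Such changes are written as at least N-fold. The number of arrays limits the precision of every value.

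A set of 26 gene lists, covering pathways of the islet and of the treatment and markers of the cell types an islet preparation holds, was fixed before the data were examined. The 25 lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether the genes of a list shifted against all other genes. Genes to be named were also chosen by a rule fixed beforehand. It took the 12 genes with the largest change in each direction among those that passed, were well above background on all 4 arrays, had no overlap between groups and carried a gene symbol that is not a clone or locus name. It added up to 3 passing members of each list per direction, or the 2 members with the highest signal where none passed, then a short fixed set in every case, with Ins1, Ins2, Irs2, Pdx1, Txnip and Gcg, and up to 5 genes per direction with a bound. Other members of the lists are named as examples, chosen after their values were seen. Some genes that the rule took are not reported here.

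The tests were tested on simulated data, with 200 genes changed in each of 20 simulations of this comparison. Mean signals were those of the 17173 genes, and spreads were drawn from the distribution that limma's eBayes fitted to them. Of genes changed 2-fold, 37.4% were recovered, and of genes changed 4-fold, 94.0%. False calls made up 4.85% of all calls. Because the spreads followed limma's own model, this share could not reveal a departure of the arrays from that model. The data had 2937 calls, many more than the genes changed here, so the recovered shares need not hold for them. A list shifted by 0.5 on the log2 scale was called in 100% of the simulations, and the 24 lists without a shift gave 0 calls. The simulated genes varied independently of each other. The simulations therefore do not show how often a list is falsely called when its genes move together. The comparison with random lists matched on mean signal was tested in the same way, for lists with the signal of the glycolysis and hypoxia genes: it singled out 20 of 20 shifted lists and 0 of 20 lists with a signal bias alone. Its matching had been refined to 100 bins of mean signal after a first simulation, made with brighter genes, in which coarser bins let a signal bias pass. That first simulation was not repeated with the finer bins, and the real list exceeded all 10000 random lists with either matching.

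The alternatives tried were normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, quantile or median scaling of the processed intensities, no scaling, no filter on dim probes, a filter on all 4 arrays, the mean of all probes of a gene, eBayes with trend and robust, least squares without moderation, the replicate number as a block, each array left out in turn, and a minimum of 1.5-fold. Normexp was planned on the mean spot signal, and the median spot signal was used in its place. A planned run on per-sample values of the authors' deposited table was not made, because the columns used from it hold group means. Scaling by the E1A spike-in control spots and changes of list membership were added after seeing the data.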

Results

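The series asked how a glucokinase activator changes gene expression in mouse pancreatic islets. The activator, called GKA in the labels, is a small molecule that raises the use of glucose by beta cells. Islets of 8-week-old C57BL/6 mice were cultured at 5.6 mM glucose for 24 h with 30 µM GKA or with vehicle, and 2 samples per group were hybridised, 1 array each. Between 23522 and 25056 probes per array, or 59.7% to 63.5% of the non-control probes, were well above background. The 75th percentile of the processed intensity was 751 and 755 on the vehicle arrays and 557 and 598 on the GKA arrays. Across genes, the log2 signals of the 2 vehicle arrays correlated with r = 0.995 and those of the 2 GKA arrays with r = 0.996, against 0.979 to 0.984 between the groups. Genes are not independent replicates, so these coefficients only describe the arrays. All 4 arrays came from 1 slide and 1 scan. The vehicle samples lay at slide positions 1 and 2 and the GKA samples at positions 3 and 4, so position and group cannot be told apart.

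The expression of a large set of islet genes differed between the GKA and the vehicle arrays. The largest rise was in S100a9, a calcium-binding protein of inflammatory cells and stressed epithelia. Its log2 fold change was 7.99 ± 0.31 (SE), or 255-fold (adjusted p = 0.00248 in limma). On the vehicle arrays S100a9 stood at -5.17 and -5.18, near the lowest values of probes well above background there, -5.91 and -5.96. The size of this fold is therefore uncertain. On the GKA arrays S100a9 stood at 2.35 and 3.28. Its partner S100a8 was not well above background on either vehicle array and was at least 19.4-fold higher with GKA (adjusted p = 0.00464). The GKA arrays differed for S100a8, with a log2 signal of -2.41 on replicate 1 and -0.90 on replicate 2. Txnip, a glucose-induced inhibitor of thioredoxin, rose by 2.49 ± 0.14 (adjusted p = 0.0035), Irs2, an adaptor of insulin signalling, by 1.21 ± 0.15 (adjusted p = 0.0125) and Pdx1, a transcription factor of the beta cell, by 1.11 ± 0.16 (adjusted p = 0.0167). Among the genes that fell were Fam196a (now Insyn2a), with a log2 fold change of -4.51 ± 0.17 (adjusted p = 0.00248; -1.91 on its other probe), and Trpm5, a cation channel of the beta cell, at -2.31 ± 0.19 (adjusted p = 0.00522). Marker genes of leukocytes, some of which islets contain, were lower too, with a median of -0.51 (camera adjusted p = 0.00406, and adjusted p = 0.699 with an estimated correlation).

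In limma, 1562 genes were higher and 1375 lower with GKA at an adjusted p under 0.05, 17.1% of the 17173 tested, and 551 of the higher and 406 of the lower genes changed by at least 2-fold. At an unadjusted p under 0.01 and at least 1.5-fold, 1368 genes were higher and 1171 lower. The groups did not overlap in 65.9% of all genes, where 33.3% is the average for arrays grouped at random. Genes on an array are not independent, so the excess over 33.3% is not a test of GKA. Directions are relative to each array's 75th percentile: without scaling, the median of all genes lay at -0.40 on the log2 scale and 747 genes were higher against 7652 lower, with spike-in scaling, added after seeing the data, the median lay at -0.61 with 425 higher against 10408 lower, and with median scaling 1379 were higher and 1851 lower. The 2937 changed genes became 1778 without vehicle replicate 1, 617 without GKA replicate 1 and 527 without GKA replicate 2.

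**Figure D1:**
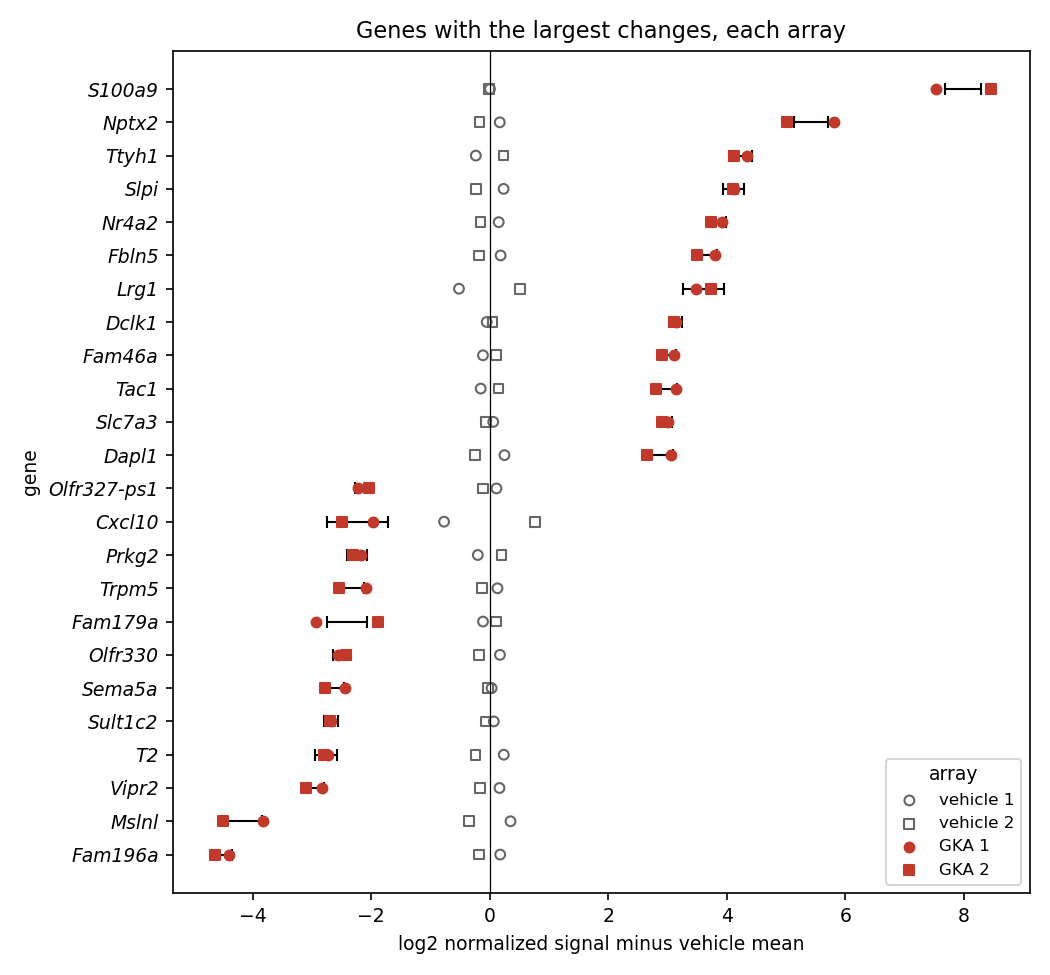
Normalized log2 signal on each of the 4 arrays, minus the vehicle mean of the gene, for the 12 genes with the largest change in each direction. Open symbols are vehicle arrays, filled symbols GKA arrays, and bars the SE of the log2 fold change around it; S100a9 sits farthest to the right, at 7.99, and Fam196a farthest to the left, at -4.51.

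After S100a9, the largest rise in the plot of genes by array was in Nptx2, a neuronal pentraxin (chromosome 5, 145317905 to 145317964), by 5.42 ± 0.29 on the log2 scale. Ttyh1, a chloride channel, rose by 4.23 ± 0.19, and Slpi, a secreted protease inhibitor, by 4.12 ± 0.18. The nuclear receptor Nr4a2 rose by 3.83 ± 0.15, the extracellular matrix protein Fbln5 by 3.66 ± 0.18 and the secreted glycoprotein Lrg1 by 3.61 ± 0.34. Tac1, the precursor of substance P, rose by 2.98 ± 0.18, and Slc7a3, a transporter of cationic amino acids, by 2.96 ± 0.12. The kinase Dclk1, at 3.13, and Dapl1, at 2.86, were also among the 12, and Fam46a (now Tent5a) rose 8.03-fold. The probes of Dclk1 disagreed in size, from 0.47 to 3.13. Nptx2 (-4.58) and Dclk1 (-4.74) had a low mean log2 signal with vehicle. Besides S100a8, Crygs was at least 12.9-fold higher, Dnahc10 (now Dnah10) at least 7.61-fold, Sgcd at least 7.50-fold and the clone-named 5330439B14Rik at least 14.5-fold. Each was not well above background on either vehicle array. The GKA arrays differed for Crygs, with a log2 signal of -1.38 on replicate 1 and -3.12 on replicate 2.

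After Fam196a, Mslnl (chromosome 17, 25885141 to 25885200) had a log2 fold change of -4.16 ± 0.32, Vipr2, a receptor for vasoactive intestinal peptide, of -2.96 ± 0.17, and the semaphorin Sema5a of -2.60 ± 0.15. The sulfotransferase Sult1c2 stood at -2.68 ± 0.12, T2 at -2.76 ± 0.18 and Fam179a (now Togaram2) at -2.40 ± 0.34. The cGMP-dependent kinase Prkg2 stood at -2.24 ± 0.17 and the chemokine Cxcl10 at -2.23 ± 0.51. Cxcl10 stood at -1.46 without vehicle replicate 2 and did not pass without GKA replicate 1 (adjusted p = 0.104) or GKA replicate 2 (adjusted p = 0.154). Olfr330, at -2.49, and Olfr327-ps1 (now Olfr224), at -2.12, are olfactory receptor genes. Fam196a (-4.58), Sema5a (-4.51), Olfr330 (-4.52) and Olfr327-ps1 (-4.95) had a low mean log2 signal with GKA. 2010110P09Rik (now Chp2) was at least 18.1-fold lower, Try5 at least 6.76-fold, Cyp2d37-ps at least 4.86-fold, Olfr328 at least 3.65-fold and Il18r1 at least 3.53-fold, each not well above background on either GKA array. All of the genes named in this and the preceding paragraph had an adjusted p under 0.05 in limma, with both GKA arrays on the same side of both vehicle arrays.

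The insulin genes and the glucagon gene did not pass. The log2 fold change was 0.31 ± 0.12 for Ins1 (adjusted p = 0.134), 0.25 ± 0.11 for Ins2 (adjusted p = 0.171) and 0.31 ± 0.12 for Gcg (adjusted p = 0.129), and all 3 lay below 0 without scaling and with spike-in scaling. Of the 39 measured genes of beta-cell identity and insulin secretion, 11 rose, 4 fell and 24 did not pass, and adjusted over the list alone 12 rose and 5 fell. The list as a whole was shifted up (camera adjusted p = 0.00406), with a median of 0.27, and had an adjusted p = 0.699 with an estimated correlation. It did not pass without the filter on dim probes. Those that rose included the prolactin receptor Prlr (2.34 ± 0.13), the peptide-processing enzymes Pam (1.97 ± 0.22) and Pcsk1 (1.77 ± 0.17), the glucose-6-phosphatase G6pc2 (1.94 ± 0.12) and the transcription factor Mafa (1.06 ± 0.14). Besides Trpm5, the incretin receptor Glp1r (-0.93 ± 0.12), the transcription factor Rfx6 (-0.72 ± 0.15) and the potassium channel subunit Kcnj11 (-0.64 ± 0.15) fell. Of 16 genes of the other islet endocrine cells, 3 rose and none fell, a count of 0, the risen genes being Etv1 (1.15), Gc (0.92) and the somatostatin gene Sst (0.83), with the same counts adjusted over the list alone (camera adjusted p = 0.0572), and the list passed with median, spike-in or normexp and quantile scaling and without vehicle replicate 1 or GKA replicate 2.

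CREB targets and immediate-early genes, which respond to cAMP and calcium, were shifted up as a list. Of 27 measured, 12 rose, 0 fell and 15 did not pass (13 rose adjusted over the list alone), with a median of 0.74 and a camera adjusted p = 0.000161. The list had an adjusted p = 0.699 with an estimated correlation. After Nr4a2 and Fam46a, the largest rises were in the transcription factors Crem (1.94 ± 0.16) and Fosl2 (1.53 ± 0.29) and the kinase Sik1 (1.64 ± 0.26). Fos, at 2.00 ± 0.77 (adjusted p = 0.131), Jun, at -0.32, and Crtc2, at -0.45, did not pass. In this list vehicle replicate 2 exceeded vehicle replicate 1 by a median of 0.30. The median deviation from the 4-array mean was -0.56 and -0.02 on the vehicle arrays, against 0.41 and 0.27 on the GKA arrays. The vehicle arrays thus lay further from each other than vehicle replicate 2 lay from GKA replicate 2. For this list, an effect of GKA and differences between islet cultures unrelated to it cannot be told apart. Of 19 glucose-responsive targets of ChREBP, the carbohydrate-sensing transcription factor, 5 rose and 4 fell (6 and 4 adjusted over the list alone), and the list was not shifted in camera (adjusted p = 0.385) but passed in fry, which tests whether its own genes move 1 way on balance (adjusted p = 0.0238), and in camera with spike-in scaling. Txnip, Thrsp (1.92 ± 0.11) and the arrestin-domain gene Arrdc4 (1.37 ± 0.18) rose, while Mlxipl, which encodes ChREBP (-1.30 ± 0.23), the fructokinase Khk (-1.20 ± 0.18) and the pyruvate kinase Pklr (-0.62 ± 0.11) fell.

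Of 33 genes of endoplasmic reticulum (ER) stress and the unfolded protein response, 14 rose, 2 fell and 17 did not pass (20 and 3 adjusted over the list alone), with a median of 0.43 and a camera adjusted p = 5.86e-05. The list had an adjusted p = 0.588 with an estimated correlation. Sdf2l1 (1.42 ± 0.11), Pdia4 (1.31 ± 0.21), Hyou1 (1.27 ± 0.17) and Manf (1.20 ± 0.12), which act in the folding of secreted proteins or are induced when it is strained, rose. Ddit3, which encodes the stress-induced transcription factor CHOP (-1.80 ± 0.22), and the pseudokinase Trib3 (-1.04 ± 0.16) fell. The chaperone genes Calr (0.42), Pdia3 (0.43) and Canx (0.17) did not pass. Of 24 genes of the NRF2 antioxidant response, 13 rose, 2 fell and 9 did not pass (14 and 2 adjusted over the list alone), with a median of 0.60 and a camera adjusted p = 0.000381. This list, too, had an adjusted p = 0.588 with an estimated correlation. The cystine transporter Slc7a11 (2.13 ± 0.18, well above background on 1 of 2 vehicle arrays), the heme oxygenase Hmox1 (1.49 ± 0.28) and the sulfiredoxin Srxn1 (1.44 ± 0.12) rose, and the glutathione enzymes Gstm1 (-1.50 ± 0.24) and Gpx1 (-0.50 ± 0.12) fell. Among 11 genes of the xenobiotic response, 4 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.106). They included Cyp1a1 (3.69 ± 0.50, well above background on 1 of 2 vehicle arrays) and Cyp1b1, at least 3.20-fold higher, both targets of the aryl hydrocarbon receptor, and Abcc4 (0.77), while the transporter Abcc3 (-1.29) fell.

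**Figure D2:**
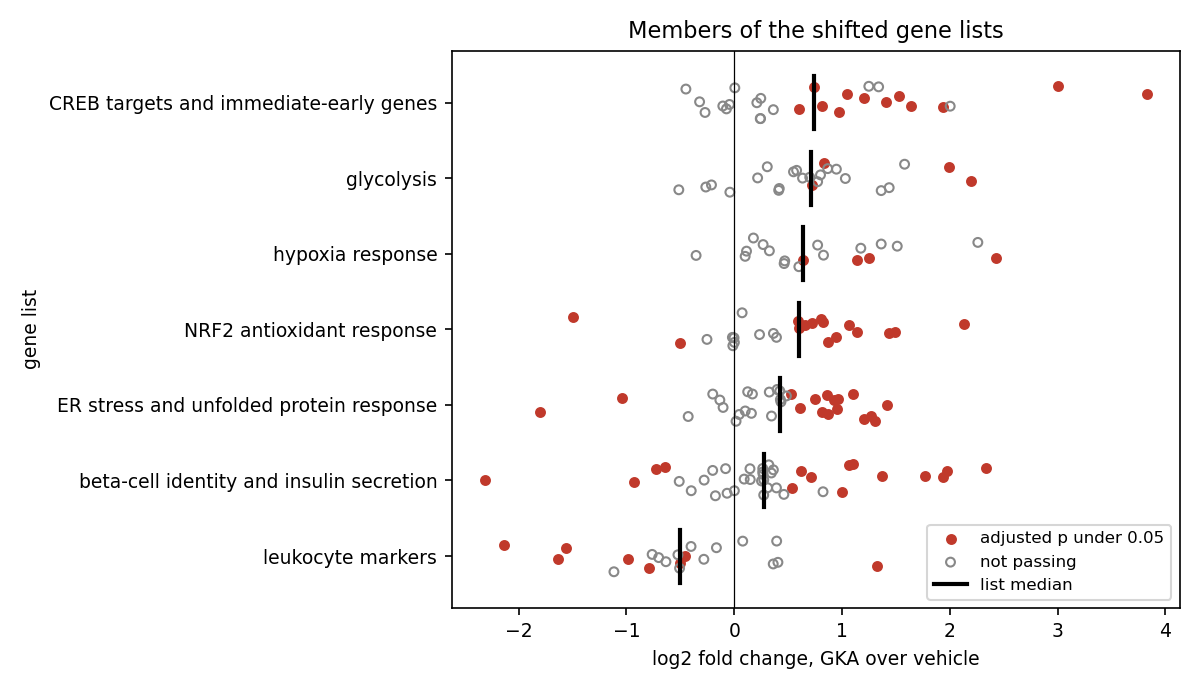
Log2 fold change, GKA over vehicle, of each measured member of the 7 shifted gene lists. Filled points passed at an adjusted p under 0.05, open points did not, and the bar is the list median, from -0.51 for the leukocyte markers to 0.74 for the CREB targets.

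Glycolytic genes and hypoxia-responsive genes were higher with GKA, and the vehicle arrays also differed from each other in both. Of 24 glycolysis genes, 4 rose, 0 fell and 20 did not pass, but 14 rose and 1 fell adjusted over the list alone, and the list was shifted up with a median of 0.71 (camera adjusted p = 0.000381). It had an adjusted p = 0.699 with an estimated correlation. Ldha, the lactate dehydrogenase subunit kept low in normal beta cells (2.20 ± 0.37), the lactate transporter Slc16a3 (2.00 ± 0.42), Pkm2 (now Pkm, 0.83 ± 0.19) and Gapdh (0.72 ± 0.15) rose. Of 19 hypoxia-response genes, 4 rose, 0 fell and 15 did not pass (9 rose and 1 fell adjusted over the list alone), with a median of 0.64 and a camera adjusted p = 0.000694. It, too, had an adjusted p = 0.699 with an estimated correlation. The peptide hormone gene Adm (2.43 ± 0.39), Ero1l (now Ero1a, 1.25 ± 0.29) and Higd1a (1.14 ± 0.23) rose, with Ero1l at 0.81 without vehicle replicate 1 and not passing without GKA replicate 1 (adjusted p = 0.131) or GKA replicate 2 (adjusted p = 0.152). Vehicle replicate 2 exceeded vehicle replicate 1 by a median of 0.54 in the glycolysis list and 0.61 in the hypoxia list, and by 1.94 in the list of inflammation and chemokine genes, of which Cxcl10 alone fell, 0 rose and 24 of 25 did not pass (camera adjusted p = 0.923, with 0 passing adjusted over the list alone).

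**Figure D3:**
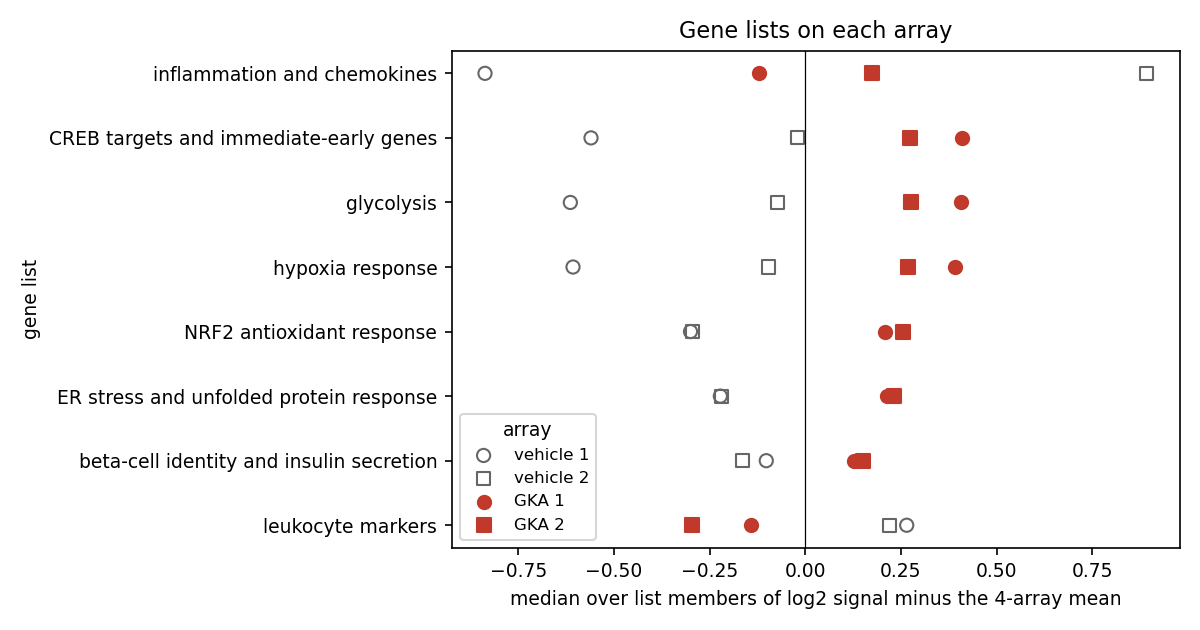
Median over list members of the log2 signal minus the mean of the 4 arrays, for the 7 shifted lists and the inflammation list, on each array. In the glycolysis list the vehicle arrays sit at -0.61 and -0.07 and the GKA arrays at 0.41 and 0.28, while in the inflammation list the vehicle arrays, at -0.84 and 0.89, enclose both GKA arrays.

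Markers of leukocytes were lower with GKA. Of 21 measured, 7 fell, 1 rose and 13 did not pass (14 fell and 2 rose adjusted over the list alone), with a median of -0.51 and a camera adjusted p = 0.00406. The list had an adjusted p = 0.699 with an estimated correlation. The lysozyme genes Lyz2 (-2.14 ± 0.30, well above background on 1 of 2 GKA arrays) and Lyz1 (-1.63 ± 0.20) and the macrophage gene Aif1 (-1.56 ± 0.28) fell, and Cd14 (1.32 ± 0.27), a receptor of monocytes and macrophages, rose. The other marker lists were not shifted in camera. Acinar cells had 2 higher and 1 lower of 15 (adjusted p = 0.947; Bhlha15 1.37, Rnase1 -0.69) and duct cells 1 and 2 of 13 (adjusted p = 0.923; Spp1 2.26, Cldn4 -0.81, Krt7 -0.79). Endothelial cells had 2 higher and 1 lower of 17, or 3 and 2 adjusted over the list alone (adjusted p = 0.923), with Cdh5 at 0.63, Emcn at -0.76 and Ramp2 at 0.54, though below 0 with spike-in scaling. Fibroblasts and stellate cells had 2 and 2 of 18, or 2 and 5 adjusted over the list alone (adjusted p = 0.281; Fn1 0.81, Col1a2 -0.87). Neural and Schwann cells had 2 and 1 of 8 (adjusted p = 0.287; Tubb3 1.05, Prph 0.89). The counts for acinar, duct and neural cells were the same adjusted over the list alone. The 3 measured red blood cell genes, too few to test as a list, did not pass, with Hba-a1 at 0.02 and Slc4a1 at 0.30, both below 0 without scaling and with spike-in scaling.

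Of 30 genes of insulin and IGF signalling, 3 rose (Irs2, Igf1r 1.04 ± 0.14, Pik3r1 0.98 ± 0.15) and 3 fell (among them Sesn2 -0.75 and Igfbp5 -0.73), with 5 and 6 adjusted over the list alone (camera adjusted p = 0.699). Of 30 S-phase and mitosis genes, 2 rose and 2 fell, or 2 and 1 adjusted over the list alone (adjusted p = 0.923). Rrm2 stood at 0.60 and Mcm7 at -0.50. Birc5 stood at 0.63, but its probes ran from -1.04 to 0.63 and it lay below 0 with normexp background correction or the mean of its probes. Tk1 stood at -0.78, well above background on 1 of 2 GKA arrays, and lay above 0 with normexp and the 75th percentile. Of 21 G1 regulators, 2 rose, E2f2 (1.20) and Ccnd1 (0.50, though below 0 with spike-in scaling), and 3 fell, among them the cell-cycle inhibitors Cdkn1c (-1.17 ± 0.21) and Cdkn2a (-1.01 ± 0.22), with Myc at -0.91, and adjusted over the list alone 2 rose and 4 fell (adjusted p = 0.354). Of 26 apoptosis regulators, 3 fell, namely the proapoptotic genes Bid (-0.86 ± 0.13) and Bbc3 (-0.73 ± 0.15) and the p53 target Trp53inp1 (-0.81 ± 0.11, and -0.16 on its other probe), and 0 rose, with the same counts adjusted over the list alone (adjusted p = 0.141), and the list passed without the filter on dim probes. Cholesterol synthesis had 4 higher and 1 lower of 24 (adjusted p = 0.115; Pmvk 0.65, Sqle 0.63, Fdps -0.59), with 7 and 1 adjusted over the list alone, and the list passed with normexp and quantile scaling. Fatty acid and triglyceride synthesis had 0 higher and 1 lower of 21 (adjusted p = 0.923; Agpat2 -0.53), and fatty acid oxidation had 0 of 22 in either direction (adjusted p = 0.923), with Acadvl at 0.30, though below 0 without scaling and with spike-in scaling. Adjusted over the list alone, 0 genes passed in both. Oxidative phosphorylation had 2 higher and 0 lower of 34, or 1 and 0 adjusted over the list alone (adjusted p = 0.577), with Cycs at 0.70 and Ndufa1 at 0.55, though below 0 with spike-in scaling. Genes disallowed in beta cells or raised on dedifferentiation had 3 higher and 0 lower of 16, or 5 and 2 adjusted over the list alone (adjusted p = 0.319; Ldha, Mgst1 0.99, Acot7 0.71).

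In all, 6 of the 25 lists tested were shifted up and 1 down with camera's preset correlation of 0.01. With an estimated correlation 0 of the 25 passed in limma, 2 had an unadjusted p under 0.05, and 3 passed in limma's fry, the ER stress, NRF2 and ChREBP lists. Without vehicle replicate 1, 11 lists passed, the 4 gained being the other islet endocrine cells, apoptosis, inflammation and fibroblast lists, and without vehicle replicate 2, 9 passed, with the inflammation and xenobiotic lists gained. The median and the mean of a list differed in sign for the inflammation list (-0.02 and 0.01, upward in camera), the endothelial list (-0.07 and 0.01, downward in camera) and the red blood cell genes (0.02 and -0.25).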

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

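The comparison of the spike-in controls was chosen after the array signals were seen. Probes that carry no gene name stood outside the gene comparison, and in limma 132 of the 2341 kept were higher with GKA and 86 lower, with log2 fold changes that are not named here because no gene goes with them. The E1A spike-in spots, also outside the comparison, were brighter on the GKA arrays by 0.22 on the log2 scale, while the 2 vehicle arrays differed by -0.27 (replicate 2 minus replicate 1). The bright corner control spots were brighter on the GKA arrays by 0.76. Their replicates differed by 0.01 in the vehicle group and 0.45 in the GKA group. Slide position and group cannot be told apart in this difference either. The 75th percentile differed by -0.38 (GKA minus vehicle) before scaling, and by -0.60 relative to the spike-ins.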

How the results depend on the processing

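Scaling by the spike-in spots and the changes of list membership were chosen after seeing the data. The main counts of 2937 changed genes, 1562 higher and 1375 lower, stayed within 1.5 times with quantile or median scaling of the processed intensities, the filter on all 4 arrays, the mean of probes and the 1.5-fold minimum. With normexp and quantile scaling 2066 genes were lower, with normexp and the 75th percentile 5040 changed and 2986 were higher, and with trend and robust 4506 changed and 2316 were lower; the cause was not tested. Without scaling 8399 changed, 747 higher and 7652 lower, and with spike-in scaling 10833, of which 425 were higher and 10408 lower, as the median of all genes moved down. Of the 10833, 1793 were among the main calls in the same direction, and 283 main calls had the opposite sign. Without the dim filter, which tests 26263 genes and has 2.37 prior degrees of freedom against 3.33, 223 changed, 156 higher and 67 lower; the share of each in the drop was not tested. Signal over background leaves only a bound for 83 higher and 81 lower genes. Least squares without moderation, with its 2 residual degrees of freedom, left 1 gene, which was higher, and 0 lower, with 4043 genes at an unadjusted p under 0.05.

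The labels do not say whether samples of the 2 groups with the same replicate number belong together. Across genes, the differences between replicates 2 and 1 of the groups correlated with r = 0.075. With 2 pairs this cannot settle whether the samples were paired. With the replicate number as a block, 1908 genes changed, 1009 higher and 899 lower, and 8 lists were called, among them all 7 called without the block, with the other islet endocrine list gained, and 24 of the genes followed singly no longer passed.

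Each array was left out in turn, with the lone sample assumed to vary like the other group. The fits gave 527 to 2835 changed genes, 313 to 1521 higher and 205 to 1314 lower. All of them used the same number of arrays, so that number cannot explain the range between them. Each fit took its residual spread only from the group left with 2 arrays, the vehicle group where a GKA array was left out. The prior degrees of freedom were 3.63 in those fits and 4.9 in the fits without a vehicle array. How much of the range this explains was not tested. Of the 119 genes followed singly, 27 no longer passed without vehicle replicate 1, 16 without vehicle replicate 2, 64 without GKA replicate 1 and 63 without GKA replicate 2. Without the dim filter 78 of them no longer passed, and with least squares 113, all that had.

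The 7 list calls became 0 with an estimated correlation, and fry called 3, of which 2 (ER stress and NRF2) were among the 7 and the ChREBP targets were gained; there were 12 with spike-in scaling (gained: other islet endocrine cells, ChREBP targets, xenobiotic response, inflammation and disallowed genes) and 7 to 11 without 1 array, where all 7 stayed called each time. Both changes of list membership left the same 7. With normexp and quantile scaling 9 were called, with the cholesterol and other islet endocrine lists gained, and with median scaling 8, with the latter gained. Quantile scaling of the processed intensities left 7. Without the dim filter 7 were called, with the apoptosis list in place of the beta-cell list.

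Of the 113 genes followed singly that passed, 108 kept their sign throughout. Birc5 turned to -0.24 with normexp and quantile scaling, -0.14 with normexp and the 75th percentile and -0.28 with the mean of its probes, and Tk1 to 0.079 with normexp and the 75th percentile. With spike-in scaling Ndufa1 stood at -0.048, Ccnd1 at -0.10 and Ramp2 at -0.057. Without scaling and with spike-in scaling, in this order, genes that did not pass turned: Acadvl to -0.088 and -0.30, Slc4a1 to -0.082 and -0.30, Ins1 to -0.075 and -0.29, Ins2 to -0.13 and -0.35, Gcg to -0.078 and -0.29, and Hba-a1 to -0.365 and -0.58. Hba-a1 also turned to -0.032 with median scaling and ranged from -0.37 to 0.41 without 1 array. The planned run on the authors' deposited table was not made, because its columns used here hold group means.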

Other observations

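The test of differences between cultures was chosen after its result was seen, and so was the finer signal matching in the test of random gene lists, whose prediction had been set down before. The tests of the neutrophil markers and of neighbouring genes were set down before their results were seen, although the neighbour pattern had been noticed in gene clusters of the same data. All genes named in the next 2 paragraphs besides those of the report were chosen after their values were seen.

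Some changed genes lay next to each other. On chromosome 11, 5 neighbouring olfactory receptor genes were lower with GKA: Olfr331 (-1.37 ± 0.14), Olfr330 (-2.49 ± 0.16), Olfr329 (at least 3.52-fold), Olfr328 (at least 3.65-fold) and Olfr327-ps1 (-2.12 ± 0.14), with probes from 58315100 to 58379905 on build mm9, while the next changed gene, Olfr324, rose 2.83-fold. On chromosome 17, Gng13 (-1.30 ± 0.26), Chtf18 (-1.10 ± 0.16), Rpusd1 (-1.56 ± 0.19), Mslnl (-4.16 ± 0.32), Msln (-0.84 ± 0.18) and Haghl (-0.84 ± 0.16) fell between 25855911 and 25919898, while Narfl between them, at -0.58 (adjusted p = 0.0842), did not pass and Lmf1, the changed gene before them, rose by 0.59 ± 0.13.

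The vehicle arrays stood apart from each other in inflammatory genes. The log2 signal of Cxcl1 was -3.42 in vehicle replicate 1 and 1.06 in vehicle replicate 2, against -1.26 and -0.49 on the GKA arrays. That of Ccl2 was -0.19 and 2.47, against 0.77 and 1.44, and that of Il6 was -1.63 and 0.41, against -1.05 and -0.20.

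Over the genome, 398 pairs of adjacent tested genes with probes at most 100 kb apart had both members changed, and in 64.1% of them, 255 pairs, both changed in the same direction. Shuffling the directions among the changed genes 10000 times gave 45.2% to 55.0%, which argues against directions placed independently of each other. The gene clusters in which the pattern had been noticed were not taken out of these pairs. Pairs on opposite strands shared their direction in 62.0% (shuffled 43.2% to 57.3%), which argues against transcription running on from a gene into the next as the whole cause. Without related symbols, clone names or same-strand probes under 10 kb apart, the share was 62.7% of 212 pairs (shuffled 43.4% to 57.1%). This argues against gene copies or double names as the whole cause. The opposite-strand pairs still held related pairs, and the unrelated pairs still held same-strand ones. Both causes acting together are therefore not argued against. A shared response of chromosomal neighbourhoods to GKA may be a source of the pattern, as a hypothesis. Differences between islet cultures unrelated to GKA were not tested as a source and stay open. A bias of the signal with regional base composition also stays open, since no probe sequences were used here.

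S100a8 and S100a9 are abundant in neutrophils, so a larger share of these cells in the GKA islets was weighed with a list of further neutrophil genes. Of 18 such genes on the array whose values had not been looked at, 7 were measured, with a median log2 fold change of 0.29 (95% bootstrap interval over genes -0.21 to 0.67), below the rise of 1 that had been set as the least a larger share would give. Among these, 2 rose, Ltf by at least 2.58-fold and Stfa3 by 0.65 ± 0.15 (well above background on 1 of 2 vehicle arrays), while the histidine decarboxylase gene Hdc fell with -1.38 ± 0.11, and 8, among them the abundant Ngp, Retnlg and Mmp8, were not well above background on any array; of the 4 markers seen earlier, Camp (-0.39), Elane (0.48), Lcn2 (1.39, also in the inflammation list) and Itgam (0.41, also in the leukocyte list), none passed. The 7 genes as a set thus did not show the rise that had been set for a larger share. Csf3r (4.25), Hdc (-1.10) and Trem1 (-1.69) already had signal on the vehicle arrays, which a small influx of neutrophils need not raise that far. A small influx is therefore not excluded. A response of islet cells or of other cells to GKA may account for the rise of S100a8 and S100a9 and was not tested.

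For the glycolysis and hypoxia genes, 41 in all, the median deviation from the 4-array mean was -0.59 and -0.09 on the vehicle arrays and 0.40 and 0.26 on the GKA arrays. The gap of 0.35 between the groups was smaller than the difference of 0.50 between the vehicle arrays, so an effect of GKA and differences between islet cultures unrelated to it cannot be told apart with 2 arrays per group. A bias that depends on signal is argued against: 0 of 10000 random lists matched on mean signal had a median as high as 0.64, and 95% of them lay between -0.16 and 0.10. An effect of GKA on glucose use in the islets may contribute and was not tested further.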
